A study of Homo sapiens with 12 samples.

How the data were processed

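The samples were 12 cultures of human dermal fibroblasts, 3 donor lines by 4 treatments (DMSO control, DMF at 50 uM, TGFb at 2.5 ng/ml with DMSO, and TGFb with DMF), harvested after 24 h of treatment that followed 16 h without serum. Per the labels' protocols, cells grew in DMEM with 10% fetal bovine serum, RNA was taken up in TRIzol, and biotin-labelled cDNA was made with a whole-transcript expression kit and terminal labelling kit for Affymetrix arrays. The array design and the probe-set definition are not given in the sources used here. Per the submitters' processing notes the arrays were processed with RMA and the affy package in R 2.15.1. RMA corrects background, makes the intensity distributions of the arrays alike and summarises probes per probe set, so the values deposited by the authors are on a log2 scale and a shift of all transcripts in one group would be removed. They ran from 0.71 to 12.94 with no missing values, array medians lay between 4.92 and 5.03, and no quantile of an array was over 0.207 from the mean quantile. No pair of arrays was identical.

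The table held 23786 probe sets, named by Entrez gene numbers. Through a gene table of the human assembly GRCh38.p14, used for names only, 22458 had 1 gene symbol, 0 had several and 1328 were unnamed here. To protect the donors 42 probe sets were left out, and 22416 genes were tested. No filter on dim genes was applied in the main setting, and whether a gene lay above background could not be read from summarised values. Of the 18 genes always to be named 17 had a row; the remaining one is not analysed here. Coordinates are not given because the annotation of the arrays is not known.

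Tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where said otherwise. The main test was limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on all 12 arrays, group means and the donor line as a fixed block (6 residual degrees of freedom), and Benjamini-Hochberg adjustment within each of 6 comparisons at a threshold of 0.05. The block follows the series design, in which the same 3 lines got all 4 treatments. As a check, deviations from group means correlated at 0.154 to 0.63 across genes in 18 pairs of arrays of the same line and different groups (mean 0.329), and at -0.541 to 0.132 in 36 pairs of different lines (mean -0.16). With no donor block TGFb versus control gave 1048 genes in place of 2190. The median SE of a log2 change was 0.172, and 0.244 for the interaction. The 6 comparisons share arrays, and donor lines are the replicates.

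The text names the 10 largest rises and the 10 largest falls among genes past the threshold that moved the same way in 3 of 3 lines, up to 4 members of each gene list by smallest p and members needed to say which moved, and 18 genes always. The 22 gene lists, from general knowledge and not from these samples, held 527 genes, of which 495 were measured. They cover TGFb response, collagens and their processing, matrix glycoproteins and proteoglycans, the contractile cytoskeleton, YAP and TAZ targets, NRF2 targets, integrated stress response, heat shock, NF-kB and inflammatory mediators, interferon-stimulated genes, cell division, cholesterol synthesis, hypoxia and glycolysis, proteases and their inhibitors, BMP response and p53 targets. The other 6 hold markers of keratinocytes, endothelium, melanocytes and Schwann cells, immune cells, pericytes and smooth muscle, and adipocytes. Some genes belong to several lists. Each list was tested with camera at a preset correlation of 0.01, which compares its members with the other genes, adjusted over the 22 lists, and again with an estimated correlation. A further planned test, fry, asks whether the members changed at all, not whether they changed more than other genes. It keeps the correlation between members. Counts of members past the threshold are given over all genes and adjusted over the list alone, and where none is given there was none.

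For the effect of DMF on TGFb-changed genes, 200 genes per direction were chosen by the moderated statistic in 2 lines and read in the line left out, with an exact two-sided sign-flip test over 3 lines. Correlations and overlaps between comparisons were set beside 20 simulations with no effect. Alternatives were no donor block, the line as a random block, only the arrays compared, median centring of each array, cyclic loess, leaving out the lower 50% of genes by mean level, an intensity trend with a robust prior, array weights, probe sets tested one by one, a 1.5-fold minimum, 50 or 500 genes in the held-out choice, and leaving out each line or array in turn. Data of 22416 genes were simulated for DMF versus control, with 50 changed at each size. The test recovered 6% at a log2 change of 0.5, 62% at 1, 90% at 2 and 98% at 3. It made 134 calls there, 6 of them false, and 0 in the unchanged TGFb comparison. Real DMF effects differed by line, so these rates may be too high.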

Results

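Genome-wide transcript levels were measured in dermal fibroblast lines grown from the skin of 3 healthy donors. Each line was kept without serum for 16 h and then treated for 24 h in 4 ways, which gave 12 arrays in 4 groups of 3. The groups were the vehicle DMSO alone (control), 50 uM dimethyl fumarate (DMF), 2.5 ng/ml transforming growth factor beta (TGFb) with DMSO, and both compounds together (TGFb+DMF). DMF is an electrophilic fumaric acid ester used as a drug, and TGFb is the cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts. The series asks which sets of genes the treatments regulate. In all 22416 named genes were tested. Changes are log2 differences with limma's moderated standard error (SE), pooled over all 12 arrays, whose number limits their precision.

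TGFb versus control asked what the cytokine alone did. It changed 2190 of 22416 genes at an adjusted p under 0.05, of which 939 rose and 1251 fell. Of the called genes 2189 moved the same way in 3 of 3 lines, as did 43.8% of all genes. The calls were made on these same lines, so this is not replication. The steepest rises were those of TSPAN2, a tetraspanin (6.58 ± 0.70, adjusted p = 0.00104), PRG4, the joint lubricant lubricin (4.28 ± 0.63, adjusted p = 0.00312), and COL10A1, a short-chain collagen (4.08 ± 0.47, adjusted p = 0.00129). The transcription regulator ID1 (4.01 ± 0.55), DACT1 (3.90 ± 0.39), the protein cross-linking enzyme TGM2 (3.79 ± 0.60), the NADPH oxidase NOX4 (3.50 ± 0.54), the matrix protein COMP (3.41 ± 0.57), PLPP4 (3.39 ± 0.33) and CCN2, also called connective tissue growth factor (3.31 ± 0.44), completed the 10 largest rises. The largest falls were those of EVI2B (-3.95 ± 0.60), KIT (-3.87 ± 0.76), PPL (-3.56 ± 0.37), CEMIP (-3.51 ± 0.35), CA12 (-3.46 ± 0.32), RAB27B (-3.41 ± 0.45), PTX3 (-3.22 ± 0.36), DCLK1 (-3.21 ± 0.55), GNA14 (-3.19 ± 0.50) and MRGPRF (-3.08 ± 0.36). KIT is the receptor of stem cell factor, CEMIP binds hyaluronan during its breakdown, CA12 is a carbonic anhydrase and PTX3 is a secreted pentraxin of innate immunity. Adjusted p ranged up to 0.0107 among these 20 genes.

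Many genes that mark the myofibroblast rose. In the TGFb response list 21 of 31 measured members rose and none fell (26 rose when adjusted over the list alone), with a median change of 1.35. SKIL (2.37 ± 0.16, adjusted p = 0.00031) and PMEPA1 (3.23 ± 0.23, adjusted p = 0.00031), which damp TGFb signalling, had the smallest p, and the inhibitory SMAD7 rose by 1.77 ± 0.20 (adjusted p = 0.00134). Of 30 contractile and cytoskeletal genes 19 rose (23 adjusted over the list alone), among them TPM1 (2.93 ± 0.25), PDLIM7 (2.13 ± 0.24), PALLD (1.68 ± 0.20) and MYLK (1.54 ± 0.23). ACTA2, the smooth muscle actin that defines myofibroblasts, rose from a log2 level of 8.78 ± 0.06 (SD, n = 3) to 9.85 ± 0.59, a 2.1-fold change (adjusted p = 0.0417). TAGLN rose 4.72-fold (adjusted p = 0.00506). Of 36 collagen and collagen-processing genes 17 rose and none fell (18 rose and 1 fell adjusted over the list alone), including the collagen-modifying enzymes PLOD2 (1.83 ± 0.23), P4HA3 (2.45 ± 0.31) and P4HA2 (1.23 ± 0.17). COL1A1 rose by 1.22 ± 0.34 (adjusted p = 0.0489), while COL1A2 was at 0.34 ± 0.15 and did not pass (adjusted p = 0.209). Of 37 matrix glycoproteins and proteoglycans 10 rose and 4 fell (20 and 5 adjusted over the list alone): elastin (ELN, 2.58 ± 0.47) and ASPN (2.37 ± 0.49) were among those that rose, CCN3 (-2.90 ± 0.39) and TNXB (-1.82 ± 0.32) among those that fell. FN1, fibronectin, was at 0.11 ± 0.12 (adjusted p = 0.657). Of 22 YAP and TAZ targets 6 rose (9 rose and 2 fell adjusted over the list alone), among them CCN1 (1.47 ± 0.19), CCN2 and ANKRD1 (2.91 ± 0.76, adjusted p = 0.0374). The coactivators themselves were at -0.42 ± 0.14 for YAP1 (adjusted p = 0.103) and 0.19 ± 0.16 for WWTR1 (adjusted p = 0.533), and the ligand gene TGFB1 at 0.72 ± 0.21 (adjusted p = 0.054).

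These lists moved up against the other genes at camera's preset correlation, with adjusted p of 2.04e-19 for TGFb response, 2.92e-15 for contractile genes, 3.71e-10 for collagens, 0.000576 for matrix glycoproteins and 0.000875 for YAP and TAZ targets. With an estimated correlation the adjusted p were 0.116, 0.099, 0.331, 0.412 and 0.161 in the same order, and none passed. In no comparison did any of the 22 lists pass with an estimated correlation, so every list call below holds only at the preset value.

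TGFb also moved metabolic and defence genes. Of 32 integrated stress response genes, targets of ATF4 that serve amino acid supply, 13 rose (19 rose and 1 fell adjusted over the list alone), including asparagine synthetase ASNS (2.39 ± 0.40), PCK2 (2.14 ± 0.38) and GARS1 (1.13 ± 0.19); the list median was 0.79. For the integrated stress response camera gave an adjusted p of 1.01e-09, and an adjusted p of 0.343 with an estimated correlation. Of 18 cholesterol synthesis genes 4 rose, SC5D (0.84 ± 0.16), SQLE (1.25 ± 0.28), STARD4 (1.18 ± 0.30) and IDI1 (0.99 ± 0.25), and 10 rose adjusted over the list alone. For cholesterol synthesis camera gave an adjusted p of 2.79e-06, and an adjusted p of 0.412 with an estimated correlation. Of 15 BMP response genes 4 rose and 1 fell (7 and 1 adjusted over the list alone): the inhibitors of differentiation ID1, ID3 (2.88 ± 0.57) and ID4 (1.77 ± 0.36) and SMAD7 rose, and the ligand BMP4 fell by 2.19 on the log2 scale. For BMP response camera gave an adjusted p of 0.0185, and an adjusted p of 0.388 with an estimated correlation. Of 28 interferon-stimulated genes 11 fell (13 fell and 2 rose adjusted over the list alone), with MX1 at -2.49 ± 0.35, OAS3 at -1.36 ± 0.15 and IFIT2 at -1.25 ± 0.20. For interferon-stimulated genes camera gave an adjusted p of 2.43e-06, and an adjusted p of 0.269 with an estimated correlation. Of 20 p53 targets 6 fell (9 adjusted over the list alone), led by XPC (-0.93 ± 0.15) and SESN1 (-0.82 ± 0.16). For p53 targets camera gave an adjusted p of 1.25e-05, and an adjusted p of 0.269 with an estimated correlation. Of 30 NRF2 targets, which code for antioxidant and detoxifying enzymes, 4 fell: AKR1C2 (-1.99 ± 0.23), EPHX1 (-1.69 ± 0.18), AKR1C3 (-1.37 ± 0.23) and BLVRB (-1.17 ± 0.21); the same 4 fell over the list alone. For NRF2 targets camera gave an adjusted p of 0.0222, and an adjusted p of 0.518 with an estimated correlation. The NRF2 gene NFE2L2 was at -0.10 ± 0.14 (adjusted p = 0.743), NQO1 at -0.33 ± 0.20 and HMOX1 at 0.46 ± 0.56, none of which passed, nor did GCLM (1.07 ± 0.40) or TXNRD1 (-0.38 ± 0.30). Heat shock genes had a median of -0.29, with 1 of 19 up (HSPB1, 0.55 ± 0.14) and 1 down (HSPA4L, -2.35 ± 0.27). For heat shock genes camera gave an adjusted p of 0.0265, and an adjusted p of 0.641 with an estimated correlation.

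Lists that did not pass camera still held changed members. Counts in this paragraph are over all genes, with those adjusted over the list alone in brackets. Of 30 NF-kB and inflammatory genes 2 rose [2], IL6 (2.02 ± 0.29) and LIF (1.72 ± 0.35), and 4 fell [6], ICAM1 (-1.59 ± 0.29), TNFAIP3 (-1.04 ± 0.22), CCL2 (-1.96 ± 0.44) and SOD2 (-1.48 ± 0.35). For inflammatory genes camera gave an adjusted p of 0.161, and an adjusted p of 0.641 with an estimated correlation. Among 27 proteases and inhibitors, 2 rose [3] and 5 fell [6], with the lysosomal protease CTSL at -1.83 ± 0.22 and the aggrecanase ADAMTS4 at 1.64 ± 0.20. For proteases camera gave an adjusted p of 0.251, and an adjusted p of 0.412 with an estimated correlation. Of 28 hypoxia and glycolysis genes 3 rose [3] and 1 fell [1], led by PFKP (1.65 ± 0.18; camera adjusted p = 0.313, and adjusted p = 0.687 with an estimated correlation). Of 38 cell division genes 1 fell [1], TYMS (-1.13 ± 0.25), and the list medians of lines 1, 2 and 3 were 0.75, 0.80 and -0.80. For cell division genes camera gave an adjusted p of 0.19, and an adjusted p of 0.742 with an estimated correlation. Markers of other cell types lay low, with mean log2 levels of 3.49 to 4.56, and none of these 6 lists passed. Their members that moved were DSP, a desmosomal protein of keratinocytes (2.06 ± 0.27), ERG of endothelium (0.91 ± 0.22), CD68 of macrophages (-0.84 ± 0.15), CD36 of the pericyte list (-1.22 ± 0.22) and the adipocyte regulator PPARG (-1.29 ± 0.18). Camera adjusted p were 0.339 for keratinocyte, 0.649 for endothelial, 0.74 for melanocyte and Schwann cell, 0.661 for immune, 0.542 for pericyte and 0.313 for adipocyte markers.

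The count for TGFb versus control was 1048 (433 higher, 615 lower) in a fit with no donor block. Leaving out a whole line gave 183 genes without line 1, 0 without line 2 and 2969 without line 3, and leaving out 1 array gave 912 without control array 1, 996 without control array 2, 985 without TGFb array 1 and 1145 without TGFb array 2. By line, in the order 1, 2 and 3, the list medians for TGFb were 1.64, 1.23 and 1.31 for TGFb response; 0.93, 0.66 and 0.38 for collagens; 0.62, 0.41 and 0.30 for matrix glycoproteins; 0.99, 0.85 and 0.64 for contractile genes; 0.58, 0.44 and 0.33 for YAP and TAZ targets; -0.49, -0.43 and 0.14 for NRF2 targets. For the other called lists they were 0.60, 0.91 and 1.09 for integrated stress response; -0.22, -0.72 and -0.02 for heat shock genes; -0.94, -0.67 and -0.54 for interferon-stimulated genes; 1.40, 1.06 and -0.08 for cholesterol synthesis; -0.07, 0.34 and 0.64 for BMP response; -0.81, -0.64 and -0.15 for p53 targets. Further counts for TGFb, as members that rose and fell over all genes [over the list alone], were 1 and 0 [2 and 0] of 13 endothelial markers. The NRF2 target call ended without the lower 50% of genes (adjusted p = 0.189), line 1 (0.135), line 2 (0.209), control array 2 (0.0678), TGFb array 1 (0.155) or TGFb array 2 (0.177). The heat shock call ended with the line as a random block (adjusted p = 0.0547), and without the donor block (0.0662), the lower 50% of genes (0.102), line 2 (0.239), control array 2 (0.0772), control array 3 (0.271), TGFb array 1 (0.191) or TGFb array 2 (0.242). The BMP response call ended without line 3 (adjusted p = 0.22), control array 3 (0.126) or TGFb array 3 (0.145). The inflammatory list, not called in the main fit, passed downward without the lower 50% of genes (adjusted p = 0.0237), line 1 (0.044), control array 1 (0.0444) or TGFb array 3 (0.0401). The cell division list, not called in the main fit, passed upward with array weights (adjusted p = 0.00325), and without line 3 (3.73e-09), control array 3 (1.48e-06) or TGFb array 3 (0.000138).

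DMF versus control asked what DMF did in cells without added TGFb. No gene passed in limma at an adjusted p under 0.05 (smallest adjusted p 0.0815), whereas 3961 of 22416 had an unadjusted p under 0.05. NRF2 targets had the smallest camera p of the 22 lists at the preset correlation, close to that of heat shock genes, with a median change of 0.63; medians in lines 1, 2 and 3 were 0.57, 0.65 and 0.37. None of the 30 members passed over all genes, and 12 passed, all upward, when adjusted over the list alone. Those with the smallest p were PGD (0.96 ± 0.15), the aldo-keto reductase AKR1B10 (2.35 ± 0.49), thioredoxin TXN (0.68 ± 0.15) and sulfiredoxin SRXN1 (2.22 ± 0.50). NQO1, the classic quinone reductase of the NRF2 programme, was at 0.66 ± 0.20 (adjusted p = 0.142 over all genes and 0.0217 over the list alone), GCLM at 1.30 ± 0.40, HMOX1 at 1.22 ± 0.56, TXNRD1 at 0.68 ± 0.30 and NFE2L2 itself at 0.22 ± 0.14. The list as a whole passed at the preset correlation (camera adjusted p = 1.22e-07, and adjusted p = 0.576 with an estimated correlation). Neither it nor any other list passed fry in this comparison (lowest adjusted p = 0.156).

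Protein folding and stress genes lay higher with DMF. Heat shock genes had a median of 0.67 and 7 of 19 passed adjusted over the list alone, among them HSPA4 (0.67 ± 0.18), STIP1 (0.97 ± 0.26) and BAG3 (1.45 ± 0.40). For heat shock genes camera gave an adjusted p of 1.65e-07, and an adjusted p of 0.623 with an estimated correlation. The median was 1.14 in line 1, 0.80 in line 2 and 0.01 in line 3. Integrated stress response genes had a median of 0.49, with 9 of 32 past the threshold adjusted over the list alone, including ATF3 (1.63 ± 0.36) and the amino acid transporter SLC7A5 (2.13 ± 0.51). For the integrated stress response camera gave an adjusted p of 7.69e-07, and an adjusted p of 0.623 with an estimated correlation. Hypoxia and glycolysis genes had a median of 0.34, and 0 of 28 passed over either set of genes; VEGFA was at 1.22 ± 0.34 and PGK1 at 0.65 ± 0.18. For hypoxia and glycolysis camera gave an adjusted p of 1.33e-05, and an adjusted p of 0.576 with an estimated correlation. Matrix glycoproteins lay lower, at -0.21, with 0 of 37 past either threshold; TNXB was at -1.18 ± 0.32 and CTHRC1 at -1.07 ± 0.30. For matrix glycoproteins camera gave an adjusted p of 0.000258, and an adjusted p of 0.623 with an estimated correlation. Interferon-stimulated genes lay lower, at -0.30, a call that ended in 11 of 25 alternatives, and 0 of 28 passed over either set. For interferon-stimulated genes camera gave an adjusted p of 0.0422, and an adjusted p of 0.697 with an estimated correlation.

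The myofibroblast lists did not pass with DMF alone. Medians were -0.07 for TGFb response (camera adjusted p = 0.952), 0.01 for collagens (0.952), 0.09 for contractile genes (0.884) and -0.15 for YAP and TAZ targets (0.259). ACTA2 was at -0.74 ± 0.29 (adjusted p = 0.22), TAGLN at 0.37 ± 0.37, COL1A1 at 0.04 ± 0.34, COL1A2 at -0.22 ± 0.15, FN1 at -0.11 ± 0.12, CCN1 at -0.10 ± 0.19, CCN2 at 0.998 ± 0.44, ANKRD1 at 1.81 ± 0.76, YAP1 at -0.01 ± 0.14, WWTR1 at 0.06 ± 0.16, TGFB1 at -0.15 ± 0.21 and SMAD7 at 0.31 ± 0.20, and none of these passed. Adjusted over the list alone, 1 of 22 YAP and TAZ targets rose and 5 fell, led by FOXF2 (-0.97 ± 0.18) and AMOTL2 (-0.73 ± 0.17). In the same way 4 of 20 p53 targets fell, led by CCNG1 (-1.33 ± 0.29), and 3 of 15 BMP response genes rose and 3 fell, with MSX1 at 1.08 ± 0.18 and BMP4 at -1.10 ± 0.30. Camera adjusted p were 0.343 for p53 targets, 0.786 for BMP response, 0.952 for inflammatory genes, 0.214 for cell division, 0.952 for cholesterol synthesis and 0.884 for proteases. For the markers of other cell types they were 0.952 (keratinocyte), 0.259 (endothelial), 0.492 (melanocyte and Schwann cell), 0.884 (immune), 0.343 (pericyte) and 0.952 (adipocyte).

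The count of 0 changed with line 3, whose DMF array had the lowest array weight of the 12 (0.383). Without line 3 the count was 3098 (1399 higher, 1699 lower), without its DMF array 2365, without its control array 255 and with array weights 1890. A fit with no donor block also gave 0, the line as a random block 2, and leaving out TGFb array 3 or TGFb+DMF array 1 gave 1. By line, in the order 1, 2 and 3, the list medians for DMF alone were -0.26, -0.29 and -0.16 for matrix glycoproteins; 0.34, 0.65 and 0.36 for integrated stress response; -0.46, -0.34 and 0.09 for interferon-stimulated genes; 0.44, 0.38 and 0.24 for hypoxia and glycolysis. Further counts for DMF alone, as members that rose and fell over all genes [over the list alone], were 0 and 0 [1 and 0] of 30 contractile genes, 0 and 0 [1 and 0] of 30 inflammatory genes, 0 and 0 [2 and 1] of 38 cell division genes, 0 and 0 [0 and 1] of 27 proteases, 0 and 0 [0 and 2] of 10 pericyte and smooth muscle markers. The interferon call ended with the line as a random block (adjusted p = 0.0654) or cyclic loess (0.0512), and without the donor block (0.0701), line 1 (0.343), line 2 (0.113), control array 1 (0.156), DMF array 1 (0.206), DMF array 2 (0.202), TGFb array 1 (0.0579) or TGFb array 3 (0.0632). The cell division list, not called in the main fit, passed upward without line 3 (adjusted p = 0.000456) or control array 3 (4.06e-07). The p53 target list, not called in the main fit, passed downward without control array 3 (adjusted p = 0.0282).

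**Figure D1:**
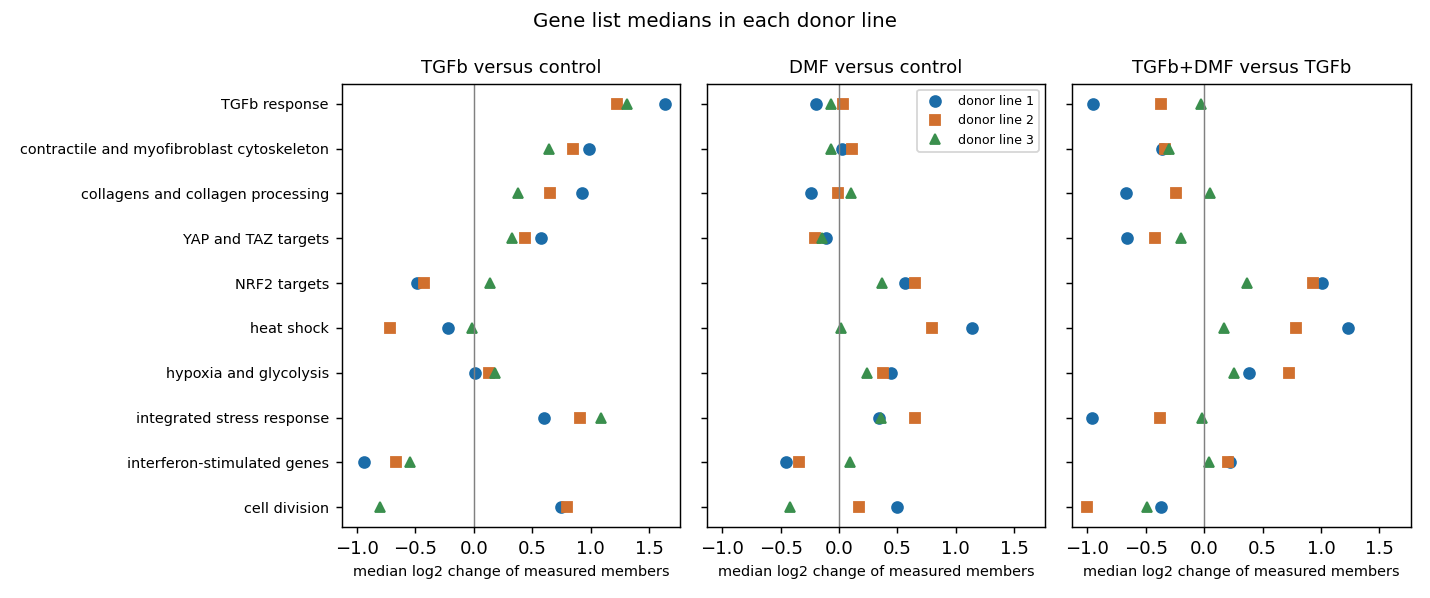
Median log2 change of the measured members of 10 gene lists, with 1 point per donor line, on a log2 x axis whose vertical line marks no change, for TGFb versus control, DMF versus control and TGFb+DMF versus TGFb. NRF2 targets lay above 0 in 3 of 3 lines when DMF was given, with or without TGFb, and contractile genes lay above 0 with TGFb and below 0 when DMF was added to it.

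TGFb+DMF versus TGFb asked what DMF did to fibroblasts that also received TGFb. It changed 80 of 22416 genes (45 rose, 35 fell), all of them the same way in 3 of 3 lines, as did 38.5% of all genes. These calls too were made on the same lines. AKR1B10 rose most (4.11 ± 0.49, 17.2-fold, adjusted p = 0.0186), followed by the secreted phosphoprotein osteopontin SPP1 (3.02 ± 0.27, adjusted p = 0.00386), the protease-activated receptor F2RL2 (2.84 ± 0.47), the microRNA gene MIR27A (2.34 ± 0.39), the tryptophan-degrading enzyme KYNU (2.27 ± 0.31), the integrin subunits ITGA2 (2.24 ± 0.34) and ITGB3 (2.22 ± 0.28), the ERK phosphatase DUSP6 (2.23 ± 0.30), PAQR5 (2.16 ± 0.29) and the decoy receptor IL13RA2 (1.99 ± 0.25). The largest falls were those of LRRN3 (-2.53 ± 0.22, adjusted p = 0.00386), MAMDC2 (-2.31 ± 0.24), the tendon transcription factor MKX (-2.08 ± 0.30), CAP2 (-1.89 ± 0.26), TSPAN18 (-1.88 ± 0.22), keratin KRT7 (-1.86 ± 0.31), the proteoglycan OMD (-1.84 ± 0.28), the amino acid transporter SLC38A4 (-1.81 ± 0.28), ACTA2 (-1.65 ± 0.29) and the fibrillar collagen COL11A1 (-1.64 ± 0.25). Adjusted p ranged up to 0.0459 in these 20 genes.

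ACTA2 fell 3.13-fold, from a log2 level of 9.85 ± 0.59 (SD, n = 3) with TGFb to 8.20 ± 0.94 with both, against 8.78 ± 0.06 in control cells. Of the 30 contractile genes 4 fell, ACTA2, CALD1 (-0.96 ± 0.16), LMOD1 (-1.27 ± 0.21) and TPM1 (-1.47 ± 0.25), and 14 fell and 1 rose adjusted over the list alone. For contractile genes camera gave an adjusted p of 4.57e-08, and an adjusted p of 0.095 with an estimated correlation. TAGLN was at -1.37 ± 0.37 (adjusted p = 0.126 over all genes, 0.00955 over the list alone). In the TGFb response list LIMS2 fell by 1.03 and 13 of 31 members fell adjusted over the list alone, with TGFB1I1 at -0.99 ± 0.21, CDH2 at -1.86 ± 0.41 and COMP at -2.37 ± 0.57; the list median was -0.50. For TGFb response camera gave an adjusted p of 2.12e-05, and an adjusted p of 0.301 with an estimated correlation. COL11A1 was the 1 collagen-list gene of 36 that fell, and 5 fell adjusted over the list alone; COL1A1 was at -0.78 ± 0.34 (adjusted p = 0.322) and COL1A2 at -0.36 ± 0.15 (adjusted p = 0.314). For collagens camera gave an adjusted p of 9e-05, and an adjusted p of 0.489 with an estimated correlation. No matrix glycoprotein passed over all genes and 11 of 37 fell adjusted over the list alone, with PRELP at -1.35 ± 0.26, CTHRC1 at -1.46 ± 0.30, VCAN at -1.59 ± 0.38 and FN1 at -0.10 ± 0.12. For matrix glycoproteins camera gave an adjusted p of 1.2e-09, and an adjusted p of 0.153 with an estimated correlation. YAP and TAZ targets had a median of -0.47, with 0 of 22 past the threshold over all genes and 10 down adjusted over the list alone, led by AMOTL2 (-0.94 ± 0.17) and IGFBP3 (-0.50 ± 0.15). For YAP and TAZ targets camera gave an adjusted p of 9e-05, and an adjusted p of 0.066 with an estimated correlation. CCN1 was at -0.56 ± 0.19, CCN2 at -1.19 ± 0.44, ANKRD1 at -1.11 ± 0.76, YAP1 at 0.23 ± 0.14, WWTR1 at 0.04 ± 0.16, TGFB1 at 0.36 ± 0.21 and SMAD7 at 0.10 ± 0.20, and none of these 7 passed over all genes.

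NRF2 targets lay higher as a list. Of 30 members 4 rose, AKR1B10, AKR1C2 (1.59 ± 0.23), EPHX1 (1.21 ± 0.18) and NQO1 (1.30 ± 0.20, adjusted p = 0.0315), and 21 rose adjusted over the list alone; the median was 0.80. For NRF2 targets camera gave an adjusted p of 2.96e-17, and an adjusted p of 0.066 with an estimated correlation. AKR1C2 and EPHX1 were also among the genes that fell with TGFb alone. TXNRD1 was at 0.97 ± 0.30, GCLM at 0.90 ± 0.40, HMOX1 at 0.64 ± 0.56 and NFE2L2 at 0.13 ± 0.14, short of the threshold over all genes. Of 28 hypoxia and glycolysis genes 2 rose, CA12 (1.97 ± 0.32) and hexokinase HK1 (0.77 ± 0.14), 9 rose adjusted over the list alone, and all 28 had a change above 0. For hypoxia and glycolysis camera gave an adjusted p of 2.85e-11, and an adjusted p of 0.066 with an estimated correlation. Heat shock genes had a median of 0.72, with 0 of 19 past the threshold over all genes and 8 over the list alone, led by HSPB8 (1.96 ± 0.40). For heat shock genes camera gave an adjusted p of 5.26e-08, and an adjusted p of 0.301 with an estimated correlation. Of 27 proteases and inhibitors CTSL rose (1.57 ± 0.22, adjusted p = 0.0262), and 10 rose and 1 fell adjusted over the list alone, with MMP1 at 1.33 ± 0.27 and MMP12 at 1.45 ± 0.30. For proteases camera gave an adjusted p of 0.00118, and an adjusted p of 0.066 with an estimated correlation. Cell division genes had a median of -0.65, with 0 of 38 past the threshold over all genes and 12 down over the list alone, led by KIF20A (-2.17 ± 0.48) and CCNA2 (-1.55 ± 0.35). For cell division genes camera gave an adjusted p of 1.12e-10, and an adjusted p of 0.301 with an estimated correlation. Integrated stress response genes had a median of -0.45; 1 rose and 1 fell of 32 adjusted over the list alone, ATF3 (1.41 ± 0.36) and ALDH1L2 (-1.33 ± 0.32). For the integrated stress response camera gave an adjusted p of 0.000124, and an adjusted p of 0.489 with an estimated correlation.

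Cholesterol synthesis genes had a median of -0.32 with 0 of 18 past either threshold, and interferon-stimulated genes a median of 0.20 with IFIT2 (0.83 ± 0.20) past the threshold adjusted over the list alone. For cholesterol synthesis camera gave an adjusted p of 0.00245, and an adjusted p of 0.489 with an estimated correlation. For interferon-stimulated genes camera gave an adjusted p of 0.032, and an adjusted p of 0.489 with an estimated correlation. In the BMP response list MSX1 rose (1.23 ± 0.18) and 3 rose and 1 fell of 15 over the list alone (camera adjusted p = 0.462, and adjusted p = 0.703 with an estimated correlation). Inflammatory genes had a median of 0.12 and a camera adjusted p of 0.0518, just short of the threshold, with IL6 against that direction at -1.31 ± 0.29. Camera gave 0.236 for p53 targets. Among markers of other cell types the immune list shifted up (median 0.11): CD68 rose (0.89 ± 0.15, adjusted p = 0.0438) and CD163 was at 1.39 ± 0.31. For immune markers camera gave an adjusted p of 0.0237, and an adjusted p of 0.144 with an estimated correlation. Both are macrophage proteins, and the list's mean log2 level was 3.92. The other marker lists did not pass, with camera adjusted p of 0.879 (keratinocyte), 0.345 (endothelial), 0.894 (melanocyte and Schwann cell), 0.879 (pericyte) and 0.214 (adipocyte).

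The 80 calls depended on lines 1 and 2: the count was 0 without line 1, 0 without line 2 and 1970 without line 3, where all 80 were kept. It was 1 in a fit with no donor block, 2 with the line as a random block, 1 with only these 6 arrays and 1837 with array weights; without 1 array it was 0 (TGFb array 1, TGFb+DMF array 1 or 2), 4 (TGFb 2), 881 (TGFb 3), 481 (TGFb+DMF 3), 33 (control 1), 5 (control 2), 24 (DMF 1), 43 (DMF 2) or 262 (DMF 3). By line, in the order 1, 2 and 3, the list medians for DMF added to TGFb were -0.95, -0.37 and -0.03 for TGFb response; -0.67, -0.24 and 0.05 for collagens; -0.94, -0.32 and -0.15 for matrix glycoproteins; -0.36, -0.34 and -0.30 for contractile genes; -0.66, -0.42 and -0.20 for YAP and TAZ targets; 1.01, 0.93 and 0.37 for NRF2 targets; -0.96, -0.38 and -0.02 for integrated stress response. For the other called lists they were 1.23, 0.79 and 0.17 for heat shock genes; 0.22, 0.21 and 0.04 for interferon-stimulated genes; -0.37, -1 and -0.49 for cell division genes; -0.49, -0.44 and 0.03 for cholesterol synthesis; 0.39, 0.72 and 0.25 for hypoxia and glycolysis; 0.18, 0.02 and 0.25 for proteases; 0.16, 0.08 and -0.04 for immune markers. The TGFb response and heat shock medians were smallest in line 3 and largest in line 1, without which they were -0.28 and 0.43. Further counts for DMF added to TGFb, as members that rose and fell over all genes [over the list alone], were 0 and 0 [1 and 1] of 30 inflammatory genes, 0 and 0 [1 and 0] of 20 p53 targets, 0 and 0 [0 and 1] of 12 keratinocyte markers, 0 and 0 [0 and 1] of 13 endothelial markers, 1 and 0 [2 and 0] of 15 immune markers. The collagen call ended without line 1 (adjusted p = 0.117). The interferon call ended with the line as a random block (adjusted p = 0.057), and without the donor block (0.0662), the lower 50% of genes (0.52), line 1 (0.0519), line 2 (0.108), TGFb array 3 (0.116), TGFb+DMF array 1 (0.053) or TGFb+DMF array 2 (0.342). The cholesterol synthesis call ended without line 1 (adjusted p = 0.0519), TGFb array 1 (0.185), TGFb array 2 (0.0813) or TGFb+DMF array 3 (0.0633). The protease call ended without the lower 50% of genes (adjusted p = 0.257). The immune marker call ended with only the arrays compared (adjusted p = 0.0524), and without line 1 (0.0701), TGFb array 1 (0.0939) or TGFb+DMF array 2 (0.0756). The inflammatory list, not called in the main fit, passed upward with only the arrays compared (adjusted p = 0.0437), cyclic loess (0.0479), array weights (0.00211) or probe sets tested one by one (0.0497), and without line 1 (0.0252), line 3 (0.000454), control array 1 (0.0447), control array 2 (0.0499), control array 3 (0.0478), TGFb array 1 (0.0134), TGFb array 3 (0.0176) or TGFb+DMF array 3 (0.00185). The adipocyte marker list, not called in the main fit, passed upward without line 3 (adjusted p = 0.0434).

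**Figure D2:**
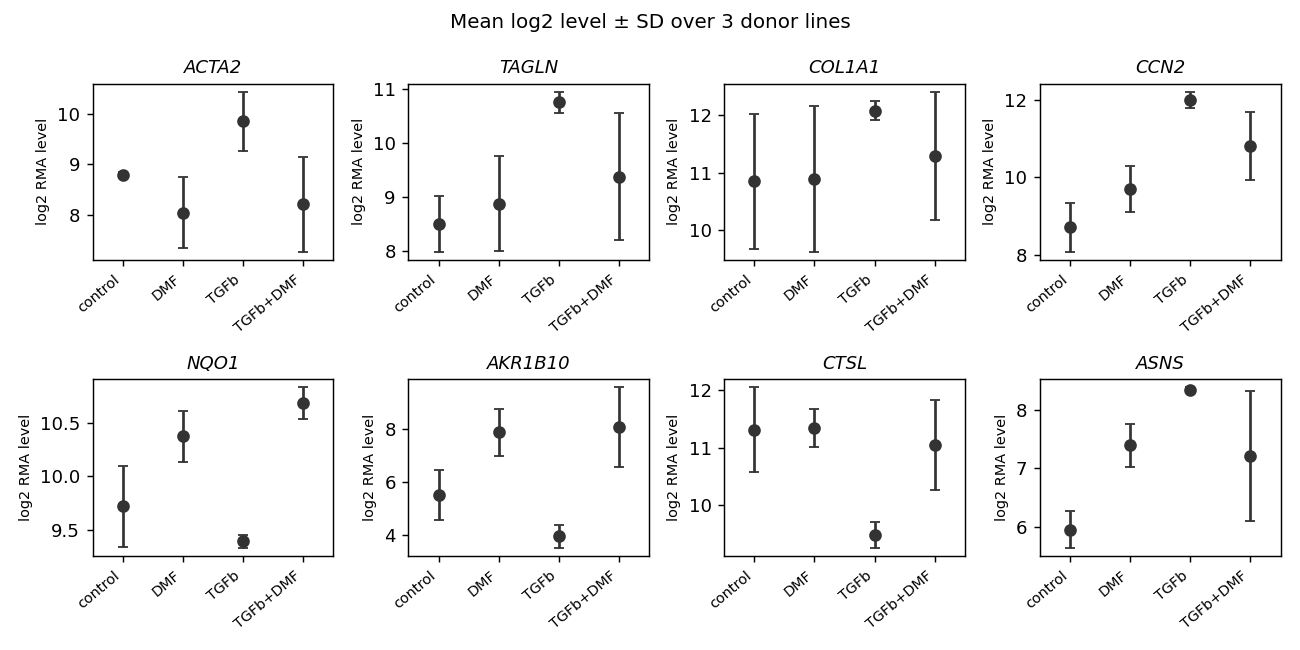
Mean log2 RMA level in each of the 4 groups for 8 genes, with bars of 1 SD over 3 donor lines. ACTA2 rose with TGFb and fell when DMF was added, while NQO1, AKR1B10 and CTSL were higher with both compounds than with TGFb alone; each panel has its own y axis, which does not start at 0.

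Some genes changed by TGFb moved the opposite way with DMF. Of the 80 genes, 51 were also called in TGFb versus control and all 51 in the opposite direction: 24 had risen with TGFb and fell with DMF, and 27 had fallen and rose. Independent lists would share 1.47 and 2.51. Both comparisons use the TGFb arrays, so part of this excess may come from their chance values; across genes the log2 changes correlated at r = -0.425 (genes are not independent replicates), against -0.499 simulated with no effect, and their covariance was -0.074 against -0.0253. In a check free of that sharing, the 200 genes with the strongest rise and the 200 with the strongest fall were chosen in 2 lines and read in the line left out. Over the risen genes the median of TGFb+DMF minus TGFb was -1.02, -0.24 and -0.08 in lines 1, 2 and 3 (mean -0.45 ± 0.51, SD, n = 3), against a mean of 0.00 for all genes. Averaged over 2 lines it was -0.16, -0.55 and -0.63 without line 1, 2 or 3, so its size rested largely on line 1. Over the fallen genes it was 0.64, 0.42 and 0.22 (mean 0.43 ± 0.21), and 0.32, 0.43 and 0.53 over the same pairs of lines. The percent of risen genes that moved down was 89.5, 63.0 and 58.5, and of fallen genes that moved up 82.0, 77.5 and 72.5. Over all genes 52.5, 49.5 and 49.0% lay below 0 and 47.4, 50.5 and 51.0% above. For each of the 2 medians the two-sided exact sign-flip p was 0.25, the smallest that 3 lines can give.

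TGFb+DMF versus DMF asked whether TGFb still acted in the presence of DMF. It changed 189 genes (117 rose, 72 fell). The rises were led by TSPAN2 (4.09 ± 0.70), PMEPA1 (3.03 ± 0.23), PLEK2 (2.71 ± 0.28), SKIL (2.59 ± 0.16, adjusted p = 0.000207), PLPP4 (2.56 ± 0.33), ADAMTS4 (2.32 ± 0.20), DACT1 (2.29 ± 0.39), the microRNA gene MIRLET7A2 (2.28 ± 0.23), PCDH9 (2.22 ± 0.43) and SCG5 (2.14 ± 0.39). The falls were led by PTX3 (-2.07 ± 0.36), ZFP36 (-2.02 ± 0.22), CABLES1 (-2.01 ± 0.19), GBP2 (-1.86 ± 0.28), SECTM1 (-1.81 ± 0.29), SIPA1L2 (-1.81 ± 0.27), MYLIP (-1.74 ± 0.28), HSPA4L (-1.73 ± 0.27), PLCB1 (-1.73 ± 0.33) and LOC389765 (-1.61 ± 0.25). ZFP36 is a protein that destabilises inflammatory mRNAs, and GBP2 is an interferon-induced GTPase. Of the 31 TGFb response genes 8 rose (17 adjusted over the list alone), including BHLHE40 (1.54 ± 0.20), SMAD7 (1.56 ± 0.20) and TGFB1 (1.22 ± 0.21, adjusted p = 0.0273), with a median of 0.95. For TGFb response camera gave an adjusted p of 5.72e-18, and an adjusted p of 0.238 with an estimated correlation. Of 36 collagen-list genes 3 rose, PLOD2 (1.60 ± 0.23), P4HA2 (1.01 ± 0.17) and COL7A1 (0.79 ± 0.15), and 6 rose over the list alone. For collagens camera gave an adjusted p of 5.75e-08, and an adjusted p of 0.293 with an estimated correlation. Of 30 contractile genes TPM1 rose (1.97 ± 0.25), 10 rose adjusted over the list alone, and ACTA2 was at 0.16 ± 0.29 and TAGLN at 0.50 ± 0.37. For contractile genes camera gave an adjusted p of 7.41e-08, and an adjusted p of 0.238 with an estimated correlation.

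Of the YAP and TAZ targets 1 of 22 rose, CCN1 (1.01 ± 0.19), with CCN2 at 1.12 ± 0.44 and ANKRD1 at -0.01 ± 0.76. For YAP and TAZ targets camera gave an adjusted p of 0.0032, and an adjusted p of 0.238 with an estimated correlation. BMP response genes had a median of 0.58 and 2 of 15 rose, SMAD7 and the BMP antagonist GREM1 (0.996 ± 0.19; camera adjusted p = 0.000292, and adjusted p = 0.238 with an estimated correlation). The remaining list shifts upward were those of matrix glycoproteins (median 0.24), cholesterol synthesis (0.37), hypoxia and glycolysis (0.18, with PFKP up by 1.47) and proteases (0.03). For matrix glycoproteins camera gave an adjusted p of 0.00951, and an adjusted p of 0.428 with an estimated correlation. For cholesterol synthesis camera gave an adjusted p of 0.000292, and an adjusted p of 0.405 with an estimated correlation. For hypoxia and glycolysis camera gave an adjusted p of 0.000463, and an adjusted p of 0.293 with an estimated correlation. For proteases camera gave an adjusted p of 0.0487, and an adjusted p of 0.283 with an estimated correlation. Downward shifts were those of cell division (-0.59), heat shock (-0.37), interferon-stimulated genes (-0.31) and p53 targets (-0.24). For cell division genes camera gave an adjusted p of 2.92e-13, and an adjusted p of 0.293 with an estimated correlation. For heat shock genes camera gave an adjusted p of 0.000463, and an adjusted p of 0.405 with an estimated correlation. For interferon-stimulated genes camera gave an adjusted p of 0.00951, and an adjusted p of 0.403 with an estimated correlation. For p53 targets camera gave an adjusted p of 0.00123, and an adjusted p of 0.293 with an estimated correlation. NRF2 targets (camera adjusted p = 0.759), integrated stress response (0.591), inflammatory genes (0.741) and the keratinocyte (0.146), endothelial (0.234), melanocyte and Schwann cell (0.391), immune (0.175), pericyte (0.564) and adipocyte (0.72) markers did not pass. COL1A1 was at 0.40 ± 0.34, COL1A2 at 0.20 ± 0.15, FN1 at 0.13 ± 0.12, NQO1 at 0.30 ± 0.20, HMOX1 at -0.12 ± 0.56, GCLM at 0.67 ± 0.40, TXNRD1 at -0.09 ± 0.30, NFE2L2 at -0.19 ± 0.14, YAP1 at -0.18 ± 0.14 and WWTR1 at 0.18 ± 0.16, none past the threshold. Of the 189 genes, 153 were also called in TGFb versus control, all in the same direction (91 up and 62 down). These 2 comparisons share the pooled SE but no array, so calls are not independent.

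The count of 189 was 46 in a fit with no donor block, 37 with only these 6 arrays and 1131 with array weights. It was 4 without line 1, 0 without line 2 and 528 without line 3, and among single arrays 27, 36 and 333 without DMF arrays 1, 2 and 3, 97, 12 and 67 without TGFb+DMF arrays 1, 2 and 3, 108 without control array 2 and 120 without TGFb array 2. By line, in the order 1, 2 and 3, the list medians for TGFb added to DMF were 0.58, 0.66 and 1.39 for TGFb response; 0.25, 0.29 and 0.30 for collagens; 0.02, 0.08 and 0.35 for matrix glycoproteins; 0.30, 0.27 and 0.48 for contractile genes; 0.12, 0.11 and 0.26 for YAP and TAZ targets; -0.27, -0.69 and -0.02 for heat shock genes; -0.08, 0.06 and -0.57 for interferon-stimulated genes. For the other called lists they were -0.29, -0.73 and -0.99 for cell division genes; 0.46, 0.77 and 0.02 for cholesterol synthesis; 0.11, 0.32 and 0.33 for hypoxia and glycolysis; 0.16, 0.01 and 0.02 for proteases; 0.24, 0.49 and 0.36 for BMP response; -0.30, -0.20 and -0.15 for p53 targets. Further counts for TGFb added to DMF, as members that rose and fell over all genes [over the list alone], were 1 and 0 [1 and 0] of 37 matrix glycoproteins, 1 and 0 [1 and 0] of 22 YAP and TAZ targets, 0 and 1 [0 and 1] of 19 heat shock genes, 0 and 0 [2 and 0] of 30 inflammatory genes, 0 and 0 [0 and 3] of 38 cell division genes, 0 and 0 [2 and 0] of 18 cholesterol synthesis genes, 1 and 0 [2 and 0] of 28 hypoxia and glycolysis genes, 1 and 0 [6 and 0] of 27 proteases, 2 and 0 [6 and 1] of 15 BMP response genes, 0 and 0 [1 and 0] of 12 keratinocyte markers, 0 and 0 [1 and 0] of 10 pericyte and smooth muscle markers, 0 and 1 [0 and 1] of 9 adipocyte markers. The matrix glycoprotein call ended with cyclic loess (adjusted p = 0.0689), and without line 3 (0.0698), DMF array 1 (0.0579) or TGFb+DMF array 3 (0.269). The YAP and TAZ target call ended without line 3 (adjusted p = 0.0651). The heat shock call ended without DMF array 1 (adjusted p = 0.0535). The interferon call ended with array weights (adjusted p = 0.281), and without the lower 50% of genes (0.0702), line 3 (0.938), DMF array 3 (0.625) or TGFb+DMF array 3 (0.269). The cholesterol synthesis call ended without line 2 (adjusted p = 0.0578) or DMF array 2 (0.0536). The protease call ended with the line as a random block (adjusted p = 0.0642), only the arrays compared (0.153), median centring (0.0535), cyclic loess (0.154) or probe sets tested one by one (0.051), and without the donor block (0.0674), the lower 50% of genes (0.054), line 1 (0.308), control array 1 (0.0653), control array 2 (0.0575), control array 3 (0.0646), DMF array 1 (0.216), TGFb array 1 (0.0613), TGFb array 3 (0.0503), TGFb+DMF array 1 (0.146) or TGFb+DMF array 3 (0.0624). The integrated stress response list, not called in the main fit, passed upward without line 1 (adjusted p = 0.0266). It passed downward with array weights (adjusted p = 0.0203), and without line 3 (5.68e-08), DMF array 3 (0.00517) or TGFb+DMF array 3 (1.98e-05). The keratinocyte marker list, not called in the main fit, passed upward without line 2 (adjusted p = 0.0403) or DMF array 2 (0.041). The pericyte marker list, not called in the main fit, passed upward without the lower 50% of genes (adjusted p = 0.0246).

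TGFb+DMF versus control gave the net change with both compounds, 2106 genes (959 rose, 1147 fell). The largest rises were those of TSPAN2 (4.03 ± 0.70), ID1 (3.97 ± 0.55), the metallothionein MT1G (3.96 ± 0.70), the microRNA genes MIR24-2 (3.96 ± 0.38) and MIR27A (3.47 ± 0.39), the growth factor HBEGF (3.69 ± 0.87), MLLT11 (3.68 ± 0.35), F2RL2 (3.59 ± 0.47), SPP1 (3.39 ± 0.27, adjusted p = 0.00061) and the cytokine IL11 (3.14 ± 0.43). The largest falls were those of KIT (-3.88 ± 0.76), ASPA (-3.31 ± 0.53), PTX3 (-3.22 ± 0.36), FAXDC2 (-3.17 ± 0.54), PPL (-3.05 ± 0.37), PLEKHG1 (-2.97 ± 0.41), TCEA3 (-2.96 ± 0.45), CYYR1 (-2.84 ± 0.50), PDGFRL (-2.83 ± 0.46) and TNFSF10 (-2.82 ± 0.59). TGFb response genes had a median above control (13 of 31 rose, 17 adjusted over the list alone, median 0.98), with SMAD7 at 1.87 ± 0.20, CCN2 at 2.12 ± 0.44 (adjusted p = 0.0159) and TGFB1 at 1.08 ± 0.21 (adjusted p = 0.0122). For TGFb response camera gave an adjusted p of 4.07e-11, and an adjusted p of 0.36 with an estimated correlation. Of 36 collagen-list genes 8 rose, 10 over the list alone, and of 30 contractile genes 10 rose, with 10 up and 1 down over the list alone. For collagens camera gave an adjusted p of 0.000188, and an adjusted p of 0.538 with an estimated correlation. For contractile genes camera gave an adjusted p of 4.99e-05, and an adjusted p of 0.396 with an estimated correlation. ACTA2 was at -0.58 ± 0.29 (adjusted p = 0.26), TAGLN at 0.87 ± 0.37, COL1A1 at 0.44 ± 0.34, COL1A2 at -0.02 ± 0.15, FN1 at 0.02 ± 0.12 and ANKRD1 at 1.80 ± 0.76, none past the threshold, and CCN1 rose (0.91 ± 0.19).

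NRF2 targets lay above control with both compounds: 9 of 30 rose, 14 up and 1 down adjusted over the list alone, including GCLM (1.97 ± 0.40), NQO1 (0.97 ± 0.20) and PGD (0.93 ± 0.15). For NRF2 targets camera gave an adjusted p of 4.99e-05, and an adjusted p of 0.418 with an estimated correlation. HMOX1 (1.10 ± 0.56), TXNRD1 (0.59 ± 0.30), NFE2L2 (0.03 ± 0.14), YAP1 (-0.19 ± 0.14) and WWTR1 (0.24 ± 0.16) did not pass. Of 28 hypoxia and glycolysis genes 9 rose and 1 fell, 16 and 1 over the list alone: VEGFA (2.12 ± 0.34), SLC2A1 (1.47 ± 0.33) and PGK1 (1.22 ± 0.18) rose and CA12 fell (-1.50 ± 0.32). For hypoxia and glycolysis camera gave an adjusted p of 5.22e-09, and an adjusted p of 0.36 with an estimated correlation. Of 15 BMP response genes 7 rose and 1 fell (camera adjusted p = 0.00223, and adjusted p = 0.418 with an estimated correlation), and the counts were the same over the list alone. Integrated stress response (0.42), cholesterol synthesis (0.41) and heat shock genes (0.23) shifted up. For the integrated stress response camera gave an adjusted p of 0.000188, and an adjusted p of 0.538 with an estimated correlation. For cholesterol synthesis camera gave an adjusted p of 0.00933, and an adjusted p of 0.651 with an estimated correlation. For heat shock genes camera gave an adjusted p of 0.0355, and an adjusted p of 0.711 with an estimated correlation. Interferon-stimulated genes (8 of 28 fell, and 11 fell and 1 rose adjusted over the list alone), p53 targets (6 of 20 fell, and 8 fell and 1 rose over the list alone) and cell division genes (3 of 38 fell over either set) shifted down. For interferon-stimulated genes camera gave an adjusted p of 0.000507, and an adjusted p of 0.418 with an estimated correlation. For p53 targets camera gave an adjusted p of 0.00223, and an adjusted p of 0.418 with an estimated correlation. For cell division genes camera gave an adjusted p of 7.95e-05, and an adjusted p of 0.538 with an estimated correlation. Camera adjusted p were 0.482 for matrix glycoproteins, 0.61 for YAP and TAZ targets, 0.954 for inflammatory genes, 0.403 for proteases, 0.419 for keratinocyte, 0.897 for endothelial, 0.911 for melanocyte and Schwann cell, 0.21 for immune, 0.539 for pericyte and 0.897 for adipocyte markers. CD163 (1.42 ± 0.31) and NOTCH3 (0.79 ± 0.19) rose and PPARG fell (-0.93 ± 0.18).

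Here the share of calls that were higher, 45.5%, became 1246 higher and 974 lower when each array was centred on its median. The count was 797 in a fit with no donor block and 1393 with only these 6 arrays; it was 33 without line 1, 0 without line 2 and 3346 without line 3, and 529, 647, 737, 630 and 1306 without control array 1, control array 2 and TGFb+DMF arrays 1, 2 and 3. By line, in the order 1, 2 and 3, the list medians for both compounds were 0.60, 0.84 and 1.35 for TGFb response; 0.00, 0.42 and 0.44 for collagens; 0.29, 0.39 and 0.49 for contractile genes; 0.55, 0.43 and 0.64 for NRF2 targets; -0.05, 0.31 and 1.17 for integrated stress response; 0.79, 0.07 and 0.02 for heat shock genes. For the other called lists they were -0.40, -0.22 and -0.51 for interferon-stimulated genes; 0.20, -0.43 and -1.46 for cell division genes; 0.62, 0.55 and -0.10 for cholesterol synthesis; 0.50, 0.65 and 0.43 for hypoxia and glycolysis; 1.04, 1.02 and 0.69 for BMP response; -0.49, -0.32 and 0.00 for p53 targets. Further counts for both compounds, as members that rose and fell over all genes [over the list alone], were 1 and 3 [2 and 5] of 37 matrix glycoproteins, 3 and 0 [4 and 1] of 22 YAP and TAZ targets, 3 and 0 [3 and 0] of 32 integrated stress response genes, 1 and 1 [1 and 1] of 19 heat shock genes, 2 and 5 [6 and 5] of 30 inflammatory genes, 1 and 0 [1 and 0] of 18 cholesterol synthesis genes, 5 and 3 [8 and 3] of 27 proteases, 1 and 0 [1 and 0] of 15 immune markers, 1 and 0 [1 and 2] of 10 pericyte and smooth muscle markers, 0 and 1 [0 and 1] of 9 adipocyte markers. The integrated stress response call ended without line 3 (adjusted p = 0.115) or TGFb+DMF array 3 (0.188). The heat shock call ended with the line as a random block (adjusted p = 0.11), median centring (0.0763) or cyclic loess (0.14), and without the donor block (0.164), the lower 50% of genes (0.107), line 1 (0.759), control array 1 (0.355) or TGFb+DMF array 1 (0.435). The cell division call ended without line 3 (adjusted p = 0.316) or control array 3 (0.468). The cholesterol synthesis call ended without line 1 (adjusted p = 0.172) or control array 1 (0.175). The BMP response call ended without control array 3 (adjusted p = 0.0627).

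The interaction asked whether DMF acted differently with TGFb than without. No gene passed in limma (smallest adjusted p 0.3), and 1684 had an unadjusted p under 0.05. At the preset correlation 11 of 22 lists differed. Integrated stress response genes had the largest gap by p, with a median interaction of -0.84: they lay higher with DMF alone and lower when DMF was added to TGFb, and 14 of 32 passed, all downward, adjusted over the list alone, led by ASNS (-2.57 ± 0.56) and PSAT1 (-1.95 ± 0.48). For the integrated stress response camera gave an adjusted p of 1.26e-14, and an adjusted p of 0.336 with an estimated correlation. Cell division (-0.86), contractile (-0.47) and TGFb response genes (-0.40) were lower than the sum of the single effects, with CDC6 at -1.29 ± 0.29, TAGLN at -1.74 ± 0.52, ACTA2 at -0.91 ± 0.41 and CCN2 at -2.19 ± 0.62. For cell division genes camera gave an adjusted p of 2.14e-13, and an adjusted p of 0.336 with an estimated correlation. For contractile genes camera gave an adjusted p of 3.42e-09, and an adjusted p of 0.168 with an estimated correlation. For TGFb response camera gave an adjusted p of 0.000105, and an adjusted p of 0.41 with an estimated correlation. So were collagens (-0.23), matrix glycoproteins (-0.10) and cholesterol synthesis (-0.32). For collagens camera gave an adjusted p of 0.00037, and an adjusted p of 0.508 with an estimated correlation. For matrix glycoproteins camera gave an adjusted p of 0.0466, and an adjusted p of 0.6 with an estimated correlation. For cholesterol synthesis camera gave an adjusted p of 0.0199, and an adjusted p of 0.6 with an estimated correlation. Proteases (0.31), interferon-stimulated genes (0.44), p53 targets (0.22) and NRF2 targets (0.15) were higher, with CTSL at 1.54 ± 0.31, MX1 at 1.65 ± 0.49 and EPHX1 at 1.14 ± 0.25. For proteases camera gave an adjusted p of 0.000197, and an adjusted p of 0.128 with an estimated correlation. For interferon-stimulated genes camera gave an adjusted p of 8.43e-05, and an adjusted p of 0.336 with an estimated correlation. For p53 targets camera gave an adjusted p of 0.0128, and an adjusted p of 0.508 with an estimated correlation. For NRF2 targets camera gave an adjusted p of 0.00716, and an adjusted p of 0.508 with an estimated correlation. The other 11 lists had camera adjusted p from 0.0507 (YAP and TAZ targets) to 0.9 (BMP response), the 6 lists of markers of other cell types among them, and CD68 was at 0.93 ± 0.22. In the hypoxia and glycolysis list CA12 was at 2.97 ± 0.46 (adjusted p = 0.306). Across genes the DMF effects with and without TGFb, which share no array, correlated at r = 0.441 (-0.002 simulated with no effect), and the TGFb effects with and without DMF at r = 0.619 (-0.003 simulated).

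The interaction count of 0 also held in a fit with no donor block and became 408 (271 higher, 137 lower) without line 3. Without the line 3 array it was 228 for DMF, 4 for TGFb and 36 for TGFb+DMF, and it was 3 with array weights. By line, in the order 1, 2 and 3, the list medians for the interaction were -0.85, -0.50 and 0.01 for TGFb response; -0.63, -0.16 and -0.11 for collagens; -0.46, -0.14 and 0.01 for matrix glycoproteins; -0.69, -0.48 and -0.17 for contractile genes; 0.40, 0.27 and -0.06 for NRF2 targets; -1.09, -1.07 and -0.34 for integrated stress response. For the other called lists they were 0.72, 0.60 and -0.07 for interferon-stimulated genes; -1.13, -1.51 and -0.08 for cell division genes; -0.54, -0.19 and 0.10 for cholesterol synthesis; 0.31, 0.32 and 0.20 for proteases; 0.42, 0.46 and -0.04 for p53 targets. In line 3 the TGFb response and cell division medians were close to 0. Further counts for the interaction, as members that rose and fell over all genes [over the list alone], were 0 and 0 [0 and 1] of 36 collagens, 0 and 0 [1 and 0] of 22 YAP and TAZ targets, 0 and 0 [2 and 0] of 30 NRF2 targets, 0 and 0 [0 and 2] of 38 cell division genes, 0 and 0 [1 and 0] of 28 hypoxia and glycolysis genes, 0 and 0 [2 and 0] of 27 proteases, 0 and 0 [1 and 0] of 15 immune markers. The collagen call ended without DMF array 3 (adjusted p = 0.0916) or TGFb array 1 (0.0909). The matrix glycoprotein call ended with the line as a random block (adjusted p = 0.251), median centring (0.0521), cyclic loess (0.0785) or array weights (0.153), and without the donor block (0.287), the lower 50% of genes (0.0773), line 1 (0.505), control array 1 (0.0685), control array 3 (0.204), DMF array 3 (0.415), TGFb array 1 (0.496), TGFb+DMF array 1 (0.31) or TGFb+DMF array 2 (0.0686). The NRF2 target call ended without the lower 50% of genes (adjusted p = 0.0516), line 1 (0.103), DMF array 3 (0.438), TGFb array 1 (0.132) or TGFb array 2 (0.108). The cholesterol synthesis call ended without line 1 (adjusted p = 0.637), control array 1 (0.363), DMF array 3 (0.724), TGFb array 1 (0.482), TGFb array 2 (0.251) or TGFb+DMF array 3 (0.135). The p53 target call ended without line 1 (adjusted p = 0.13), line 2 (0.102), control array 1 (0.0879), control array 2 (0.08), TGFb array 1 (0.146) or TGFb+DMF array 3 (0.0614). The YAP and TAZ target list, not called in the main fit, passed downward with an intensity trend and robust prior (adjusted p = 0.0421), array weights (0.0398) or probe sets tested one by one (0.0499), and without the lower 50% of genes (0.0455), line 3 (0.00832), DMF array 1 (0.0247), TGFb array 3 (0.00969) or TGFb+DMF array 3 (0.0137). The heat shock list, not called in the main fit, passed upward without TGFb array 3 (adjusted p = 0.0497). It passed downward without DMF array 3 (adjusted p = 0.0252). The inflammatory list, not called in the main fit, passed upward without control array 1 (adjusted p = 0.0426), DMF array 2 (0.0258), TGFb array 3 (0.0205) or TGFb+DMF array 3 (0.0063). The hypoxia and glycolysis list, not called in the main fit, passed upward without line 1 (adjusted p = 0.0161), DMF array 1 (0.0095), TGFb array 3 (0.00796), TGFb+DMF array 1 (0.0397) or TGFb+DMF array 3 (0.0262). The immune marker list, not called in the main fit, passed upward without control array 2 (adjusted p = 0.0486) or TGFb+DMF array 3 (0.0409). The pericyte marker list, not called in the main fit, passed upward without the lower 50% of genes (adjusted p = 0.00438).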

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

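The tests in this part were chosen after the results they bear on had been seen, and some replaced earlier versions. A first held-out bound took risen and fallen genes together and asked for a mean beyond 1 SD over lines; the bound used here asks, per direction, for all 3 lines and a mean beyond 2 standard errors. By the first bound the risen genes' -0.518 (SD 0.507) would have argued against an equal effect of DMF without TGFb, and by the second it stays open. First tests of the integrated stress response, the highest line median of TGFb+DMF minus TGFb (-0.02) and the mean of TGFb+DMF minus DMF (-0.025), left their explanations open and were replaced. The first of them is used again here, as a mean over lines, for a ceiling of each probe set. A second test of a ceiling, the share of members in the top 5% of genes with TGFb (40.6%), does not measure saturation and was dropped. The bound on a common ceiling first asked that no member lack room, which 1 member did in lines 1 and 2, and by it the explanation would have stayed open. The test of exchanged arrays first looked at 1 line. A test of compressed values, an interval over resampled genes, held no noise between arrays and was dropped with the conclusion drawn from it.

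DMF changed fewer genes in donor line 3. The SD of DMF minus control over genes was 0.571, 0.539 and 0.328 in lines 1, 2 and 3, and 1700, 1492 and 246 genes moved at least 2-fold, whereas for TGFb the SDs were 0.62, 0.556 and 0.541. Limma's F test over lines called 0 genes with a line-dependent effect of DMF and 0 of TGFb (2372 and 1419 at an unadjusted p under 0.05, with 4 residual degrees of freedom). Exchanged DMF and control arrays, or a line without DMF, stay open. The NRF2 target median lay at percentile 100 of 10000 random lists of matched level in 3 of 3 lines, with and without TGFb. Such lists hold no noise between arrays, so this cannot decide. Compressed values stay open, because the line has 1 array per treatment. Across genes the slope of line 3 on the mean of the other lines was 0.583 for TGFb minus control, 0.082 for DMF minus control and 0.18 for TGFb+DMF minus TGFb, which does not use its DMF array. A smaller response of this line and a lower effective dose in its cultures both stay open and were not tested.

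Some genes changed by TGFb moved the opposite way when DMF was added. For the fallen genes, fall-back of genes chosen on the same arrays is argued against, since in lines left out of the choice they lay above all genes by 0.431 on average (0.661, 0.417 and 0.215). An effect of DMF as large without TGFb is argued against for them as well (difference 0.813, SD 0.568, n = 3). A large part of that difference came from DMF alone, which moved these genes by -0.601, -0.612 and 0.053 in lines 1, 2 and 3 (mean -0.387, SD 0.381), down like TGFb in 2 of 3 lines. For the risen genes both stay open: the means, -0.443 and -0.518, had the same sign in 3 of 3 lines but were within 2 standard errors of 0, with lines from -1 to -0.085 for the first. With 3 lines no exact test can go below 0.25, and a damping of the TGFb response by DMF was not told from falls with each compound that are less than additive together.

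Integrated stress response genes had a median of 0.34, 0.651 and 0.358 in lines 1, 2 and 3 with DMF alone, and -0.964, -0.382 and -0.02 when DMF was added to TGFb, and their interaction median was -0.842. A single line or array as the source is argued against, since over 15 fits without a line or an array the highest adjusted p was 8.29e-09 (without control array 3) and medians ran from -1.071 to -0.557. That p rests on the preset correlation, and the adjusted p was 0.336 with an estimated correlation. A ceiling common to all probe sets of an array is argued against. On the TGFb arrays the median member lay 3.93, 4.11 and 3.87 below the highest gene in lines 1, 2 and 3, and less each member's own change with DMF alone the median room was 3.39, 3.18 and 3.27 (mean 3.278, SD 0.11). By that count 1, 1 and 0 of 32 members had no room left. A ceiling of each probe set would stop a rise but not lower a level. It stays open, because the line medians of TGFb+DMF minus TGFb were below 0 in 3 of 3 lines but their mean (-0.455, SD 0.476) was within 2 standard errors of 0. An interplay of both compounds on this programme is a candidate explanation that was not tested otherwise.

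The other lists whose interaction passed at the preset correlation are given as values. Their medians were -0.401 for TGFb response, -0.226 for collagens, -0.102 for matrix glycoproteins, -0.469 for contractile genes, -0.864 for cell division, -0.323 for cholesterol synthesis, 0.147 for NRF2 targets, 0.437 for interferon-stimulated genes, 0.311 for proteases and 0.216 for p53 targets. None of them passed with an estimated correlation.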

How the results depend on the processing

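All alternatives were planned. No called direction of a named gene turned in any of them: 5983 values of called genes stayed past the threshold, 2069 lost it, and 561 of genes not called gained it. For lists called at the preset correlation 1499 values held, 188 lost the call and 1 turned by the direction that camera gives; 52 of the others gained a call, 1512 stayed and 2 turned. With no donor block the counts were 1048 for TGFb versus control, 1 for TGFb+DMF versus TGFb, 46 for TGFb+DMF versus DMF and 797 for TGFb+DMF versus control, and DMF versus control and the interaction stayed at 0. The line as a random block gave 2 for DMF versus control and 2 for TGFb+DMF versus TGFb. Only the arrays compared gave 1 for TGFb+DMF versus TGFb, 37 for TGFb+DMF versus DMF and 1393 for TGFb+DMF versus control; fewer arrays leave fewer degrees of freedom. Array weights gave 1890, 1837, 1131 and 3 for DMF versus control, TGFb+DMF versus TGFb, TGFb+DMF versus DMF and the interaction. Without the lower 50% of genes TGFb+DMF versus TGFb gave 153. Without 1 line or 1 array the counts ran from 0 to 3098 (DMF versus control), 0 to 2969 (TGFb versus control), 0 to 1970 (TGFb+DMF versus TGFb), 0 to 528 (TGFb+DMF versus DMF), 0 to 3346 (TGFb+DMF versus control) and 0 to 408 (interaction), the highest each time without line 3. These fits hold fewer samples, and the other causes were not tested. With 500 genes per direction 72.3% of fallen genes moved back (77.3% with 200). The correlation of DMF effects was 0.32 to 0.469 and that of TGFb effects 0.433 to 0.646 without 1 line. The lists that turned by camera's direction were integrated stress response in TGFb+DMF versus DMF (median -0.066, from -0.484 with adjusted p = 5.68e-08 without line 3 to 0.187 with adjusted p = 0.0266 without line 1), interferon-stimulated genes there (-0.313, from -0.42 to -0.011, adjusted p = 0.938 without line 3) and heat shock in the interaction (-0.086, from -0.279 to 0.146, adjusted p = 0.0497 without TGFb array 3). Medians changed sign in 3 called lists, each time with the call lost: proteases in TGFb+DMF versus DMF (0.025; -0.063 without line 1 and -0.016 with cyclic loess), matrix glycoproteins in the interaction (-0.102; 0.028 without TGFb+DMF array 1) and BMP response in TGFb versus control (0.219; -0.003 without TGFb array 3). Signal over background cannot be read from these values, so limits for dim genes are unknown.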

Other observations

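The counts over other splits of the arrays were planned. Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. For TGFb versus control 1 split, the real one, gave as many genes (2190, highest other 0). The same held for TGFb+DMF versus TGFb (1 split, 80 genes, highest other 0), TGFb+DMF versus DMF (1 split, 189, highest other 1) and TGFb+DMF versus control (1 split, 2106, highest other 0). For DMF versus control and for the interaction, 10 of 10 splits gave as many as the real one, 0 genes, and the highest other was 0. The lines pair the arrays, and among splits that part all 3 pairs as the real one does the highest other count was 0 in each comparison.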
